A study of Mus musculus with 18 samples.

How the data were processed

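RNA from sorted naive CD4+ T cells of 18 mice was labelled with Cy3 and measured on Agilent 4x44k mouse arrays, 1 mouse per array and 3 mice per group. The 6 groups were WT, LAT KO and Y136F after 1 or 4 weeks of tamoxifen, as named by the sample labels. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.5.1.1, and the processed signal used here is a background-corrected intensity in linear units. Per the labels, the authors used Feature Extraction 10.5 and limma. The deposited series matrix holds log2 values with column medians between 8.558 and 8.57, which rank the probes of each array like its median intensity; they were used as an alternative only.

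From the processed intensity, log2 values were taken, the 75th percentile of each array's 43379 non-control spots was subtracted, and spots marked as outliers (187 to 952 per array, 7888 in LAT KO replicate 3 of 1 week) were left out. Spots of 1 probe were averaged, which concerned 245 of 41174 probes. The files give accessions and no gene symbols, so symbols were taken by accession from a RefSeq gene table of assembly GRCm38.p6. As the array design refers to build mm9, no coordinates are given. The match named 24844 probes (17178 genes) and left 16330 unnamed, among them any probes for immunoglobulin constant regions. Of several probes of a gene the brightest on average was used, and a probe had to be well above background on at least 3 arrays, which left 31623 genes and unnamed sequences, 17062 of them named. The number of arrays limits the precision.

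Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0, data.table version 1.17.8), with 1 mean per group over all 18 arrays, an intensity trend in the prior variance, 12 residual degrees of freedom and a median of 5.43 prior degrees of freedom. The comparisons were LAT KO and Y136F against WT and against each other at each time, the change of each mutant effect between times, and WT between times. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The 24 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals; 110 list tests over the 9 comparisons passed the preset version and 16 the estimated one. The direction given for a list is relative to all other genes. The lists cover T cell signalling (TCR-induced early response, TCR complex and proximal signalling, NFAT and NF-kB induced cytokines), T cell states (naive programme, memory and effector, Th2, regulatory, anergy and inhibitory receptors, recombination), responses (interferon, gamma-chain cytokine, proliferation, glycolysis, cholesterol synthesis, p53, unfolded protein, heat shock), other cell types (B, plasma, myeloid, CD8 T, NK, erythroid) and sex-linked genes. Lists, comparisons, tests and most alternatives were chosen before the data were examined.

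Genes are named by a fixed rule: Lat in all groups, Nr4a1 and Irf4, up to 10 rises and 10 falls of largest size per mutant comparison with WT (5 in the other comparisons) among called genes whose arrays lie wholly on one side of the compared group, and the list members with the smallest p. A fold against a group not above background is given as a lower bound.

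Alternatives were normexp background correction, quantile normalization, the series matrix, other probe rules, slide as a random or fixed term, sex as a term, a block for the replicate number, models with only the groups of a comparison, no intensity trend, array weights, female mice only and each array left out in turn. Kept outlier spots, the percent of spots well above background as a term and 2 sets of left-out arrays were added after the data were seen. The normexp step was planned on mean spot intensity, which the files at hand do not hold, and used the median intensity with an offset of 50. Array weights were estimated gene by gene, since the default method gave 1 array a weight of 0.00. The method was tested on simulated data with known changes placed in the 1-week LAT KO comparison (25042 genes, 50 per fold size). It recovered 12% of 1.5-fold, 38% of 2-fold, 86% of 4-fold and 88% of 8-fold changes, with 2 false calls. This count holds for the simulated noise only and is no measure of error control in the real arrays. For the real arrays of that comparison, 4 of the 10 splits, the real one included, gave at least as many genes as the real split, with up to 4747. Figures were drawn with matplotlib.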

Results

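Gene expression was measured in naive CD4+ T cells (CD44low, sorted from spleen) of 18 mice on single-colour Agilent mouse arrays. LAT is the membrane adaptor that links the T cell receptor (TCR) to its downstream pathways. Tamoxifen, given for 1 or 4 weeks, removed Lat through an inducible Cre (LAT KO) or left only an allele with the Y136F change, which takes away the tyrosine that binds phospholipase C-gamma 1 (Y136F). By the sample titles, WT and LAT KO mice were LAT f/- (a floxed and a null allele) and Y136F mice were LAT f/m (a floxed and a mutant allele). WT mice thus carried functional LAT from the floxed allele only. Each of the 6 groups held 3 mice, spread over 5 slides. The 75th percentile of the signal lay between 1124 and 1896 intensity units per array, and 84.2% to 97.9% of the spots were well above background. By the labels, all Y136F mice were female and all 4-week WT and LAT KO mice were male. Each 1-week WT and LAT KO group held 2 female mice and 1 male. Sex-linked genes contradicted this label in LAT KO replicate 1 of 1 week and LAT KO replicate 2 of 4 weeks. An exchange of these arrays between the times stays open, and all LAT KO results follow the labels. Sample titles gave the WT mice as Cre-negative and the series text gave them as Cre-positive, so an effect of Cre itself cannot be separated from that of the mutations if the titles hold.

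Lat transcript was lower in LAT KO cells than in WT cells at both times and higher in Y136F cells, but none of these 4 differences passed the threshold. Scaled log2 signal at 4 weeks was 3.59 ± 0.28 (SD, n = 3) in WT, 2.71 ± 0.42 in LAT KO and 4.07 ± 0.31 in Y136F. At 1 week it was 3.19 ± 0.39 in WT and 4.25 ± 0.07 in Y136F, and 2.75 ± 0.44 in LAT KO when a spot marked as an outlier was kept. Exact two-sided permutation tests with that spot kept gave p = 0.2 for LAT KO at 1 week and p = 0.1, the smallest that 3 against 3 mice allow, for the other comparisons with WT. Lat fell by 1.37 ± 0.23 (SE) on the log2 scale in LAT KO against Y136F cells at 4 weeks (limma adjusted p = 0.00275). Where the Lat probe lies relative to the deleted part of the gene is not stated in the files, so the signal is no measure of how complete the deletion was.

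After 1 week immediate TCR target genes were lower in LAT KO than in WT cells, the comparison that asks what LAT-dependent signals maintain in resting T cells. Egr2 fell by 2.44 ± 0.27 on the log2 scale (SE, n = 3 per group; adjusted p = 0.000861) and Egr1 fell by 2.32 ± 0.27 (0.000861). Nr4a1, which encodes Nur77, fell by 2.02 ± 0.15 (adjusted p = 5.96e-06) and Irf4 fell by 2.02 ± 0.23 (0.000861); both were genes that the study followed. Egr3 fell by 1.52 ± 0.21 (adjusted p = 0.00984) and the synaptophysin gene Syp fell by 1.20 ± 0.19 (0.0397). These 6 genes were the only ones past the threshold among 31561 tested by limma, 0 of them higher, with 905 at an unadjusted p under 0.05. All 6 were lower in every LAT KO array than in every WT array.

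**Figure D1:**
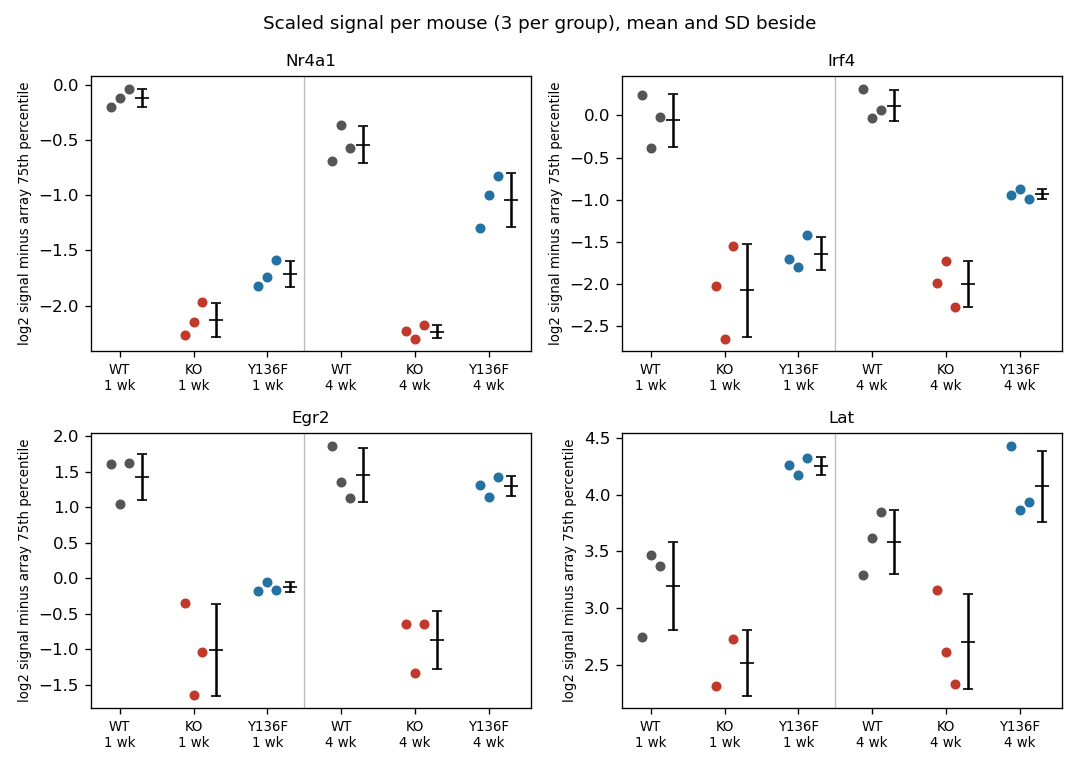
Scaled log2 signal (array 75th percentile at 0) of Nr4a1, Irf4, Egr2 and Lat in each mouse of the 6 groups, with the mean and SD of the group beside the points. Group means of Nr4a1 were -0.12 in WT, -2.13 in LAT KO and -1.72 in Y136F at 1 week, and -0.54, -2.24 and -1.04 at 4 weeks.

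Among the fixed gene lists at 1 week of LAT loss, the TCR-induced early response list moved down and the interferon response list moved up. Of 28 measured early response genes, 5 fell, 0 rose and 23 were not called; adjusted over the list alone, 12 fell and 0 rose (median -0.42, camera adjusted p = 6.5e-18, adjusted p = 0.0071 with an estimated correlation). All 41 interferon response genes had a positive difference (median 0.59, camera adjusted p = 8.44e-49, adjusted p = 0.047 with an estimated correlation), and 24 rose adjusted over the list alone. None of the 41 passed over all genes; Irf7 differed by 1.25 ± 0.3 (adjusted p = 0.504) and Oas3 by 1.27 ± 0.31 (0.52). The anergy and inhibitory receptor list, which shares Egr2, Egr3 and Nr4a1 with the early response list, had 3 of 23 genes lower (median -0.31, adjusted p = 0.06 with an estimated correlation). No regulatory T cell gene of 23 passed over all genes, and 5 fell adjusted over the list alone (median -0.4, adjusted p = 0.26 with an estimated correlation). Tnfrsf9 differed by -1.67 ± 0.36 and Gpr83 by -1.08 ± 0.22. LAT KO replicate 1 did not share the fall of this list: its mean deviation was 0.24, against -0.39 and -0.76 in the other 2 arrays and 0.03 to 0.23 in WT. For the anergy list it was 0.04, against -0.46 and -0.47, with WT at 0.11 to 0.24. The memory and effector list had a median of 0.38 over 39 genes (adjusted p = 0.36 with an estimated correlation), which rested on LAT KO replicate 1: its mean deviation was 0.61, against -0.53 and -0.4 in the other 2 arrays. In that array the B cell markers were high as well (mean deviation 0.65, against -0.53 and -0.34). B cell (median 0.25, camera adjusted p = 5.9e-05), myeloid (0.26, 3.88e-06), CD8 T cell (0.19, 0.00562) and NK cell markers (median -0.02, mean 0.18, called higher, 0.00737) were each lost with an estimated correlation (adjusted p = 0.47, 0.49, 0.11 and 0.61). With only the 6 arrays of the comparison in the model, none of the 6 genes passed (Nr4a1 adjusted p = 0.072, Egr2 0.22, Irf4 0.44). Syp ended past the threshold in 11 of 22 alternative settings and Egr3 in 17, the lost ones including those without WT replicate 3 or LAT KO replicate 2 for both genes.

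After 4 weeks of LAT loss the same 6 genes were lower and 4 of 41 interferon response genes were higher. The interferon list call was lost with an estimated correlation (adjusted p = 0.087). Egr2 fell by 2.33 ± 0.27 (SE, n = 3 per group; adjusted p = 0.00103), Irf4 by 2.12 ± 0.23 (0.000847) and Nr4a1 by 1.7 ± 0.15 (8.86e-05) on the log2 scale. Egr1 fell by 1.7 ± 0.27 (adjusted p = 0.0177), Syp by 1.64 ± 0.19 (0.00103) and Egr3 by 1.39 ± 0.21 (0.0169). Slc22a2, Wnt10a, Sh3gl3 and Apol9b fell by 1.5 to 0.93. In the interferon response list, genes of a defence against viruses, Oas2 rose by 2.44 ± 0.39 (adjusted p = 0.0179), Oas3 by 1.91 ± 0.31 (0.0179), Irf7 by 1.82 ± 0.3 (0.0179) and Stat2 by 1.35 ± 0.23 (0.0278). Oas2 was at -0.62 at 1 week and -0.8 at 4 weeks in LAT KO, and at -1.56 and -3.25 in WT. Irf7 was at 3.04 and 2.91 in LAT KO, and at 1.79 and 1.08 in WT. For both genes the larger difference at 4 weeks thus went with lower WT levels. No gene passed for the change of the LAT KO effect between times. Outside that list Ifitm3 rose by 1.77 ± 0.33 (adjusted p = 0.0491), Parp12 by 1.61 ± 0.23, Slc16a5 by 1.27 ± 0.2, Slco3a1 by 1.26 ± 0.16, Helz2 by 1.21 ± 0.19 and Znfx1 by 1.19 ± 0.2. In total 31 of 31574 tested genes and unnamed sequences changed, 18 higher and 13 lower, or 58.1% higher; in the deposited series matrix values it was 26 higher and 10 lower.

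Within the fixed lists at 4 weeks of LAT loss, 39 of 41 interferon response genes had a positive difference (median 0.83). Of them 4 rose over all genes, 0 fell and 37 were not called, and 32 rose adjusted over the list alone (camera adjusted p = 2.92e-40, adjusted p = 0.087 with an estimated correlation). Of the 28 early response genes 5 fell and 23 were not called; adjusted over the list alone, 11 fell (median -0.51, camera adjusted p = 1.2e-10, adjusted p = 0.056 with an estimated correlation). The anergy list held the same 3 called genes, Egr2, Egr3 and Nr4a1 (median -0.28, adjusted p = 0.67 with an estimated correlation). No regulatory T cell gene passed over all genes (median -0.45, adjusted p = 0.76 with an estimated correlation); Tnfrsf9 differed by -1.8 ± 0.36 (adjusted p = 0.0733) and Cd83 by -1.08 (0.146). Genes of the TCR complex and proximal signalling had a median of 0.11 (35 genes, camera adjusted p = 0.000179, adjusted p = 0.76 with an estimated correlation), with Tec at 0.65 ± 0.16 (0.184). Cholesterol synthesis, the naive programme and gamma-chain cytokine genes were called higher, and proliferation and heat shock genes lower, all lost with an estimated correlation (adjusted p = 0.73 to 0.86). Markers of the other cell types were not called (B cell 0.533, myeloid 0.153, plasma cell 0.647). Leaving out 1 array gave 5 genes (without WT replicate 3 or LAT KO replicate 2), 8 (LAT KO replicate 1), 11 (WT replicate 2), 14 (LAT KO replicate 3) or 38 (WT replicate 1), and the interferon genes Oas2, Irf7, Oas3 and Stat2 lost their calls in several of these. Wnt10a passed in 5 of 23 settings, Slc22a2 in 9 and Ifitm3 in 11, and with sex in the model Wnt10a (adjusted p = 0.054), Ifitm3 (0.059) and Apol9b (0.095) did not pass. Egr2, Irf4, Nr4a1, Syp and Slco3a1 passed in all 23.

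Y136F cells after 1 week had lower Nr4a1, Irf4 and Egr3, 3 of the early response genes lower in LAT KO cells, in the comparison that asks what signalling through phospholipase C-gamma 1 contributes. Nr4a1 fell by 1.6 ± 0.15 (SE, n = 3 per group; adjusted p = 0.000217), Irf4 by 1.59 ± 0.23 (0.0226) and Egr3 by 1.47 ± 0.21 (0.0226) on the log2 scale. The cation transporter gene Slc22a2 fell by 1.78 ± 0.28 (adjusted p = 0.0404). Egr2 differed by -1.56 ± 0.27 (0.0732) and Nr4a3 by -2.02 ± 0.35 (0.0672). With 1 unnamed sequence that rose, 5 of 31567 passed in limma, and 1908 had an unadjusted p under 0.05. Of the 28 early response genes 3 fell and 25 were not called; adjusted over the list alone, 11 fell (median -0.36, camera adjusted p = 3.24e-11, adjusted p = 0.04 with an estimated correlation). All 41 interferon response genes had a positive difference (median 0.83, camera adjusted p = 4.22e-51, adjusted p = 0.04 with an estimated correlation); none passed over all genes and 32 rose adjusted over the list alone, with Isg20 at 1.47 ± 0.3, Irf7 at 1.37 ± 0.3 and Ly6a at 0.79 ± 0.15. The anergy list held 2 lower genes (Egr3, Nr4a1; median -0.3), and the regulatory T cell list 0 over all genes and 7 lower adjusted over the list alone (median -0.41); both were lost with an estimated correlation (adjusted p = 0.34 and 0.44). Proliferation (median 0.17) and cholesterol synthesis genes (0.1) were called higher and heat shock genes lower (-0.3; Hsph1 at -1.5 ± 0.28), all lost with an estimated correlation (adjusted p = 0.44, 0.37 and 0.55). Memory and effector (camera adjusted p = 0.0087), B cell (0.0188), myeloid (0.0489), TCR complex, naive programme and unfolded protein genes (0.0285 for each of the last 3) were called higher with medians of 0.01 to 0.07. These calls too were lost (adjusted p = 0.62 to 0.79 with an estimated correlation). Without any 1 of the 3 Y136F arrays 2 genes passed, and without WT replicate 2 or 3 it was 3. With female mice only, which leaves 2 WT mice, 0 genes passed in limma and single genes were not followed. Nr4a1 passed in the 23 other settings, whereas Slc22a2, Irf4 and Egr3 lost their calls without most single arrays, and with sex in the model Slc22a2 (0.11) and Irf4 (0.063) did too.

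**Figure D2:**
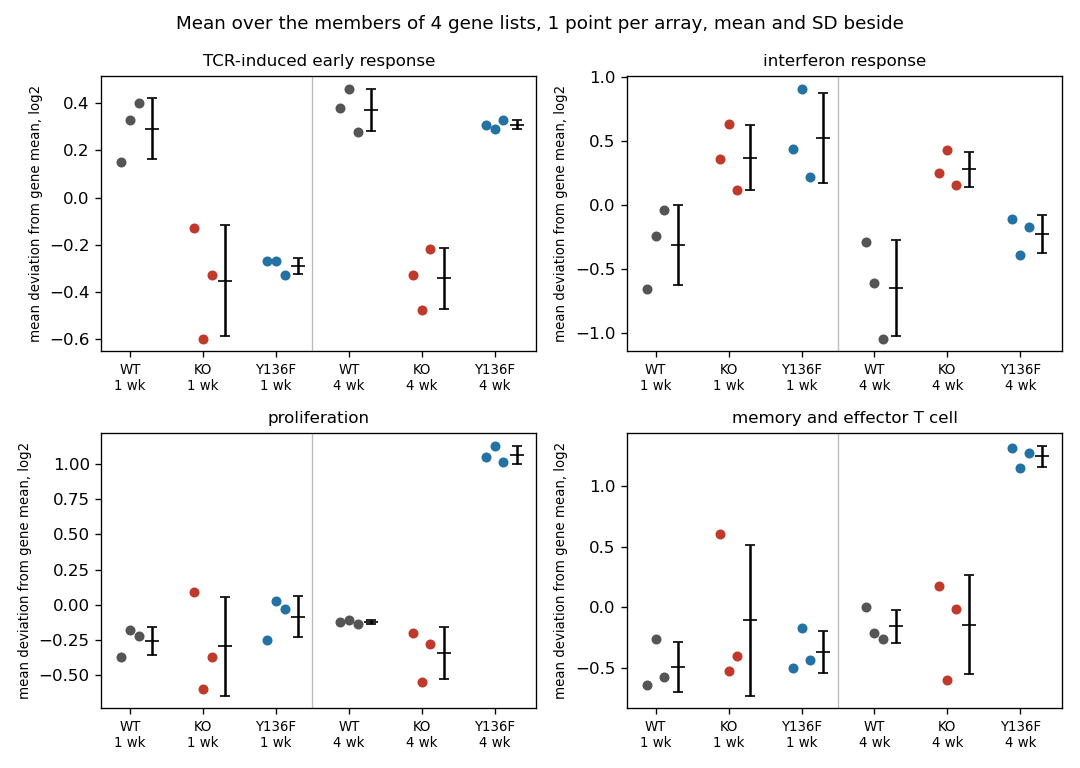
Mean deviation of 4 gene lists from each gene's mean over all arrays (log2) in each of the 18 arrays, with the mean and SD of each group beside the points. The early response list lay at 0.15 to 0.46 in all WT arrays and at -0.6 to -0.13 in all LAT KO arrays and 1-week Y136F arrays; the proliferation list lay at 1.01 to 1.13 in the 4-week Y136F arrays and at or below 0.09 elsewhere.

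After 4 weeks, Y136F cells had higher levels of cell cycle genes and of single effector genes, and lower levels of single genes of naive cells, than WT cells. Gzma (granzyme A) rose by 6.64 ± 0.61 on the log2 scale (SE, n = 3 per group), or 99.6-fold (adjusted p = 1.04e-05), and Gzmb rose by 3.81 ± 0.54 (0.000699). The chemokine gene Ccl1 rose by 3.9 ± 0.5 (adjusted p = 0.00028) and the growth factor gene Csf1 by 3.46 ± 0.46 (0.000397), with the histamine receptor gene Hrh4 at 3.63 ± 0.44 (0.000193) and the ephrin gene Efna5 at 4.38 ± 0.65 (0.000968). Sostdc1 rose by 4.97 ± 1, Cpa3 by 3.98 ± 0.82, Slpi by 3.7 ± 0.61 and the mitotic kinase gene Aurkb by 3.3 ± 0.58. A second Slpi probe differed by -0.29. Trim12a fell by 6.05 ± 0.23 on the log2 scale, or 66.5-fold (adjusted p = 5.71e-11); its other probe differed by -1.42. Dapl1, a gene of naive T cells, fell by 2.93 ± 0.23 (adjusted p = 1.96e-06) and Igfbp4 fell by 2.06 ± 0.22 (4.7e-05). Lhfpl1, Ncmap, Rab6b, Adam23, Ankrd33b and Drd1 fell by 2.13 to 3.57, and Y-linked Sly was at least 31.8-fold lower. In total 1070 of 31553 tested changed, 781 higher and 289 lower, of which 635 by at least 2-fold; 689 had a gene name.

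The early response genes were not called as a list in 4-week Y136F cells. The change of the Y136F effect from 1 week lost its list call with an estimated correlation (adjusted p = 0.056). Irf4 was lower (-1.05 ± 0.23, adjusted p = 0.0156), while Nr4a1 was at -0.49 ± 0.15 (0.101). Of the 28 genes 3 rose, among them Jun (1.9 ± 0.34, 0.00369) and Jund (0.79, 0.02), 2 fell, among them Nfkbia (-0.56, 0.0312), and 23 were not called (median -0.24, camera adjusted p = 0.875). Adjusted over the list alone, 4 rose and 5 fell. In the NFAT and NF-kB cytokine list 4 of 23 rose, Ifng by 2.67 ± 0.44, Tnfsf8 by 1.57, Tnfsf14 by 1.43 and Nfatc1 by 0.89 (list adjusted p = 0.087 with an estimated correlation). TCR complex genes went both ways, with Cd6 and Trat1 higher and Cd247 and Grap2 lower (2 and 2 of 35, camera adjusted p = 0.0461, adjusted p = 0.6 with an estimated correlation). Gene lists for anergy (3 of 23 higher, Pdcd1 by 2 ± 0.39 and Rnf128 by 1.3; 0.21 with an estimated correlation) and gamma-chain cytokine response (2 of 22 higher, Cish by 1.09 and Jak3 by 0.71; 0.19) kept no call with the estimated correlation. In the regulatory T cell list Entpd1 rose and Gpr83 fell (1 and 1 of 23, camera adjusted p = 0.0553), and in the recombination list Dntt fell (1 of 23, 0.934). Interferon response genes had a median of 0.35, with Oas3 (1.54) and Ly6a (0.58) higher (2 of 41; adjusted p = 0.21 with an estimated correlation).

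Proliferation genes rose together in 4-week Y136F cells. Of 44 genes 30 rose, 0 fell and 14 were not called, and 37 rose adjusted over the list alone (median 1.14, camera adjusted p = 2.17e-47, adjusted p = 0.005 with an estimated correlation). Mki67 rose by 2.37 ± 0.3 (adjusted p = 0.000253), Top2a by 2.1 ± 0.28 (0.000394), Cenpa by 1.54 ± 0.19 (0.000253) and Stmn1 by 1.41 ± 0.18 (0.000262). Memory and effector genes rose in 20 of 39 and fell in 1, with 26 and 1 adjusted over the list alone (median 1.25, camera adjusted p = 6.02e-30, adjusted p = 0.053 with an estimated correlation); examples were Lgals3 (2.54 ± 0.23, 1.04e-05), Itgb1 (2.31 ± 0.27, 0.00013) and Bhlhe40 (2.07 ± 0.23, 9.84e-05). Th2 genes Gata3 (1.59 ± 0.2, 0.000203), Nfil3 (1.99, 0.000436) and Areg (2.07, 0.00459) rose, 3 of 17 and 5 adjusted over the list alone (median 0.57, adjusted p = 0.12 with an estimated correlation). Naive programme genes fell in 7 of 29 and rose in 0, with 11 lower and 2 higher adjusted over the list alone (median -0.27, adjusted p = 0.15 with an estimated correlation), among them Ccr7 (-1.36 ± 0.16, 0.000111) and Actn1 (-1.2 ± 0.13, 8.66e-05).

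Metabolic and stress lists had a few called members each in 4-week Y136F cells, and none of these lists kept its call with an estimated correlation. Cholesterol synthesis genes rose in 4 of 25, such as Fdps (0.78) and Sqle (0.77), and in 13 adjusted over the list alone (median 0.48, adjusted p = 0.054 with an estimated correlation). Glycolysis and nutrient uptake genes rose in 3 of 23 (Tpi1 0.97, Slc1a5 0.73, Pgam1 0.66; adjusted p = 0.12 with an estimated correlation). Unfolded protein response genes rose in 3 of 25 (Xbp1 1.31 ± 0.25, Sdf2l1 1.18, Creld2 1.13; 0.11). Heat shock genes fell in 3 of 17 (Dnajb4 -0.89, Dnajb1 -0.75, Dnaja1 -0.74; adjusted p = 0.19 with an estimated correlation). Among p53 targets 3 of 27 rose, such as Phlda3 (1.41) and Cdkn1a (0.84), and Sesn1 fell (-1.23; adjusted p = 0.21 with an estimated correlation).

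Markers of other cell types moved unevenly in 4-week Y136F cells. Plasma cell list genes rose in 6 of 13 and fell in 1, which was Irf4 (median 0.83, camera adjusted p = 9.61e-07, adjusted p = 0.047 with an estimated correlation): Jchain rose by 3.19 ± 0.53 (0.00204), and Xbp1 and Creld2 belong also to the unfolded protein list. B cell genes were not called as a list (median -0.25, camera adjusted p = 0.833), with Pou2af1 at 0.73 (0.0496) and Cd72 at -0.59 (0.0393). Myeloid (2 of 29, S100a8 and Lilrb4a; camera adjusted p = 0.0192), CD8 T cell (2 of 7, Gzmk and Cst7; 0.0159) and NK cell genes (2 of 19, Gzma and Eomes; 0.00793) had single high members and lost their list calls with an estimated correlation (adjusted p = 0.6, 0.12 and 0.4). No erythroid gene of 18 passed (camera adjusted p = 0.362). No list for mast cells or basophils was among the fixed lists. Hdc, the gene of the enzyme that makes histamine, was named after its values were seen: it was at 1.47 ± 0.15 (SD, n = 3) in Y136F and -1.75 ± 0.32 in WT, a rise of 3.23 ± 0.22 (SE; adjusted p = 4.42e-07). Such cells also express Cpa3 and Hrh4, which rose as well. In a list of their other markers written after these values were seen, limma called 0 of 10 higher (median -0.1). The 2 at an unadjusted p under 0.05 were Cma1 (0.89) and Mcpt4 (0.99). Cd3e lay between 4.16 and 4.42 in all 6 groups and Cd4 between 2.62 and 2.98, and the sort marker Cd44 was at 1.24 ± 0.03 (SD, n = 3) in Y136F and 0.72 ± 0.41 in WT.

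Sex-linked genes separated 4-week Y136F from WT, as the labelled sexes differ: Xist was at least 241-fold higher and Uty at least 53.8-fold lower (list of 5 genes, median -6.23, adjusted p = 0.21 with an estimated correlation). With the labelled sex in the model 85 genes passed, 83 of them among the 1070. This term rests on the 1-week WT and LAT KO groups, where LAT KO replicate 1 contradicts its label. It left Xist at 6.33 (limma adjusted p = 0.52) and Uty at -2.22 (0.83), so a lost call cannot be put down to sex. Of 78 called genes followed with this term 16 kept their calls and 62 lost them. Gzma (5.55), Hrh4 (4.11), Trim12a (-6.22), Dapl1 (-3.01), Lgals3 (2.39), Bhlhe40 (2.08), Gata3 (1.6) and Ccr7 (-1.52) were among those kept. Calls were lost for Mki67 (1.91, adjusted p = 0.076), Top2a (1.6, 0.11), Aurkb (3.6, 0.11), Cpa3 (5.44, 0.054), Efna5 (3.64, 0.15), Slpi (3.25, 0.18), Sostdc1 (3.58, 0.44), Ccl1 (3.32, 0.072), Csf1 (2.75, 0.11), Gzmb (3.25, 0.12), Ifng (2.18, 0.21), Jchain (2.71, 0.19) and Irf4 (-0.64, 0.6). Without single arrays 562 (WT replicate 2), 569 (WT replicate 3), 598 (Y136F replicate 3), 669 (Y136F replicate 2) or 703 genes passed (Y136F replicate 1), and Cpa3 lost its call without Y136F replicate 2 (3.27, 0.067). Other named genes passed in part of the settings: Drd1 in 10 of 22, Uty in 12, Sly in 13, Xist and S100a8 in 14, and of 23 Rnf128 in 10, Pou2af1 in 11, Nfkbia and Ly6a in 12, Adam23, Cd72 and Grap2 in 14, Dntt in 15, and Ankrd33b and Dnajb1 in 16.

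**Figure D3:**
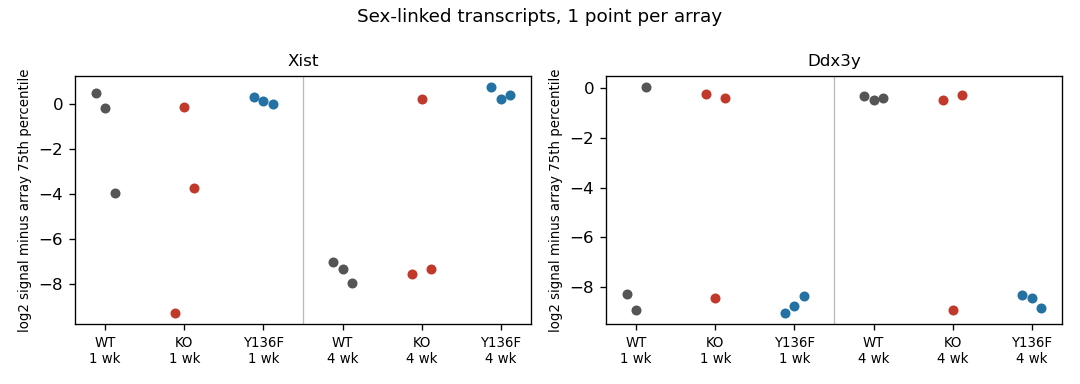
Scaled log2 signal (array 75th percentile at 0) of Xist and Ddx3y, 1 point per array in the 6 groups. Each LAT KO group has 1 array on the side opposite to its sex label, at -9.3 and 0.21 for Xist.

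Between LAT KO and Y136F cells no gene passed the threshold at 1 week, and 1063 did at 4 weeks. The change of this difference between the times was not tested, so these counts do not show that it grew. At 1 week limma called 0 of 31546, with 1802 at an unadjusted p under 0.05, and 144 passed with array weights. Lat had the smallest p (-1.72 ± 0.26, adjusted p = 0.0845; LAT KO n = 2). Nr4a1 differed by -0.42 and Irf4 by -0.43 (adjusted p = 0.857 for both), Upk3b by 2.44 ± 0.53 and Saa3 by 2.16 ± 0.48. Preset-correlation calls for lower proliferation (-0.14), naive programme (-0.15), cholesterol synthesis (-0.15), interferon response (-0.16) and TCR complex genes (-0.09), and for higher memory and effector (0.22), Th2 (0.33), heat shock (0.17) and sex-linked genes (4.49), were lost with an estimated correlation (adjusted p = 0.73 to 0.8). At 4 weeks 1063 of 31571 differed, 329 higher and 734 lower in LAT KO, and 643 of these were also called between Y136F and WT. Both comparisons use the same Y136F arrays, which can raise this overlap. Trim12a was higher in LAT KO by 6.55 ± 0.23 (SE, n = 3 per group; adjusted p = 1.5e-11), followed by Rab6b (2.66 ± 0.43), Dapl1 (2.3 ± 0.23), Lhfpl1 (2.29 ± 0.23) and Amigo2 (2.02 ± 0.32). Gzma was lower in LAT KO (-4.41 ± 0.61, adjusted p = 0.000437), with Cpa3 (-4.09 ± 0.82), Efna5 (-3.94 ± 0.65), Hrh4 (-3.93 ± 0.44) and Sostdc1 (-3.86 ± 1). Nr4a1 was lower in LAT KO than in Y136F cells (-1.2 ± 0.15, 0.000238), as were Irf4 (-1.07 ± 0.23, 0.0139), Egr2 (-2.17 ± 0.27, 0.000237) and Egr1 (-2.14 ± 0.27, 0.000237).

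As groups at 4 weeks, proliferation genes were lower in LAT KO than in Y136F cells in 34 of 44 (39 adjusted over the list alone; median -1.43, adjusted p = 0.0012 with an estimated correlation), such as Mki67 (-2.54 ± 0.3) and Ccna2 (-2.24). Early response genes were lower in 10 of 28 and higher in 0 (13 and 1 adjusted over the list alone; median -0.55, adjusted p = 0.019 with an estimated correlation), among them Dusp6 (-1.04). Memory and effector genes were lower in 20 of 39 and higher in 1, with Ccr2 (-2.94 ± 0.37), Lgals3 (-2.54) and Itgb1 (-2.36) in front, and anergy genes were lower in 10 of 23, with Lag3 (-2.31) and Pdcd1 (-2.13); both kept their calls (adjusted p = 0.02 with an estimated correlation). Naive programme genes were higher in 9 of 29 and lower in 0, such as Igfbp4 (1.83), Actn1 (1.39) and Ccr7 (1.11; 0.02 with an estimated correlation). Th2 genes were lower in 5 of 17 (Nfil3 -2.15, Areg -1.92, Gata3 -1.18; adjusted p = 0.023 with an estimated correlation), cytokine genes of the NFAT list in 4 of 23 (Ifng -2.42, Tnfsf8 -1.2; 0.031) and plasma cell genes in 7 of 13 (Slpi -3.52, Jchain -3.01; 0.0056). Interferon response genes were higher in 5 of 41 (Oas2 1.69, Oasl1 1.55, Usp18 1.07; adjusted p = 0.22 with an estimated correlation). Glycolysis (2 of 23 lower), regulatory T cell (4 of 23 lower), myeloid (4 of 29 lower) and NK cell genes (4 of 19 lower, 1 higher) lost their list calls (0.11, 0.15, 0.3 and 0.28). So did cholesterol synthesis, unfolded protein, p53 target, gamma-chain cytokine and CD8 T cell genes, called lower, and heat shock genes, called higher (0.14 to 0.42). With sex in the model, under the same limits as for Y136F against WT, 167 genes passed. Of 40 called genes followed 22 kept their calls and 18 lost them. The lost ones were Gzma (-3.33, adjusted p = 0.099), Efna5 (-3.2, 0.16), Sostdc1 (-2.47, 0.43), Irf4 (-1.48, 0.051), Dusp6 (-1.04, 0.079), Gata3 (-1.19, 0.088), Areg (-2.61, 0.1), Pdcd1 (-1.5, 0.25), Slpi (-3.07, 0.16), Jchain (-2.53, 0.17), Ifng (-1.92, 0.2), Tnfsf8 (-0.63, 0.33), Rab6b (1.91, 0.18), Amigo2 (1.95, 0.086), and Oas2, Oasl1, Usp18 and Ifit2 (1.01 to 1.37; 0.16 to 0.3). Nor was the NFAT list called (camera adjusted p = 0.17). Without LAT KO replicate 2, 441 genes passed, and Sostdc1 (-2.7, 0.3) and Cpa3 (-3.44, 0.065) lost their calls; without Y136F replicate 1 or 2 it was 588 or 632.

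The change of each effect from 1 to 4 weeks was tested as a difference of differences. For Y136F, 164 genes passed, 124 with a higher and 40 with a lower log2 difference at 4 weeks than at 1 week. Gzma gained 4.87 ± 0.87 log2 units (adjusted p = 0.0138), Ccl1 4.22 ± 0.7 (0.0101), Csf1 4.05 ± 0.65 (0.00764) and Nr4a1 1.11 ± 0.22 (0.0267), while Trim12a (-6.52 ± 0.33, 5.67e-09) and Dapl1 (-2.92 ± 0.32, 0.000417) had lower differences at 4 weeks. Proliferation genes gained in 3 of 44, and in 27 adjusted over the list alone (median 0.89, adjusted p = 0.014 with an estimated correlation), with Mki67 at 2.2 and Stmn1 at 1.51. Plasma cell genes gained in 1 of 13 and in 7 adjusted over the list alone (0.014 with an estimated correlation). Memory and effector genes gained in 6 of 39 and lost in 1 (Lgals3 2.59, Itgb1 2.25, Prf1 -1.13; adjusted p = 0.06 with an estimated correlation), and naive programme genes lost in 4 of 29 (Igfbp4 -1.93, Ccr7 -1.43; 0.056). Early response genes gained in 1 of 28, and in 9 adjusted over the list alone (median 0.56, 0.056 with an estimated correlation); Th2 genes gained in 2 of 17 (Nfil3 2.7, Gata3 1.94; 0.12). For LAT KO, limma called 0 genes, with 1614 at an unadjusted p under 0.05; Efhd2 differed by -2.94 ± 0.46, H13 by 0.8 ± 0.18 and Olfr1026 by -2.56 ± 0.57 (adjusted p = 0.815). Its list calls, such as myeloid (-0.46), B cell (-0.52) and interferon response genes (0.26), were lost with an estimated correlation (adjusted p = 0.85). With sex in the model, again under these limits of the labelled sex, 50 genes passed for Y136F. Of 24 called genes followed 9 kept their calls and 15 lost them. Among the lost were Gzma (4.15, adjusted p = 0.082), Ccl1 (3.84, 0.063), Csf1 (3.58, 0.059), Nr4a1 (1.23, 0.053), Mki67 (1.9, 0.11), Stmn1 (1.28, 0.06), Itgb1 (1.78, 0.06) and Prf1 (-1.02, 0.061). Without Y136F replicate 1 of the 1-week group 61 passed. Over all settings Nr4a1 passed in 17 of 29, Mki67 in 18, Gzma in 26, Ccl1 and Csf1 in 28, and Trim12a and Dapl1 in all 29.

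Between WT cells of the 4-week and 1-week groups limma called 0 genes, with 6107 at an unadjusted p under 0.05. Interferon response genes had a median of -0.29 (camera adjusted p = 2.29e-07), with Oas2 among them, and all 21 B cell genes a positive difference (median 0.65, 0.00104). Myeloid genes were at 0.41 (camera adjusted p = 0.0069), TCR complex genes at -0.11 and cholesterol synthesis genes at -0.18 (0.000762 for both), and naive programme genes at -0.11 (0.0213; Tob1 -1.08 ± 0.21). All of these list calls were lost with an estimated correlation (adjusted p = 0.85). Over all genes the median difference was 0.21, and quantile normalization reduced it to 0.06; the same step took the medians of Y136F against WT from -0.12 to -0.02 at 1 week and from -0.19 to -0.08 at 4 weeks, and that of LAT KO against WT at 4 weeks from -0.17 to -0.06.

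Egr3, Irf4 and Nr4a1, 3 genes, were lower than WT in both LAT KO and Y136F cells at 1 week. At 4 weeks 7 genes were higher in both, among them Oas3, Ifitm3, Parp12 and Slco3a1, and 6 were lower in both, among them Irf4, Syp and Slc22a2. Across genes, which are not independent replicates, the differences correlated with r = 0.33 at 1 week and r = 0.55 at 4 weeks. Both effects use the same 3 WT arrays, which can raise r and the number of shared calls. Simulated unchanged groups with a shared control gave r = 0.51 at the median, with lower and upper limits of -0.34 and 0.91. Both observed r lay within these limits. The simulated values were the same for both times and thus did not rest on the WT arrays of either time. How large an r these WT arrays alone would give was therefore not tested. With sex in the model the 4-week r was -0.07.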

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

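The tests of sex, T cell share, array brightness and mast cells or basophils, and both tests on Trim12a, were chosen after the results were seen. The splits of the arrays and the test of plasma cells were chosen before. Brightness here and below means the percent of spots well above background.

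The Y136F effect differed between the time points, by the test of the difference itself, in 164 genes. The differences were 4.87 for Gzma, 4.67 for Efna5, 4.22 for Ccl1, 4.05 for Csf1, 3.98 for Slpi, -6.52 for Trim12a, -4.19 for Trim55, -2.92 for Dapl1, -2.39 for Adh1, -2.38 for Zfp608 and 1.11 for Nr4a1 (log2). Trim55 was at -2.04 (adjusted p = 0.91) with outlier spots kept, and Zfp608 at -2.09 (0.19); other probes of Slpi and Zfp608 gave 0.3 and -0.18. Efna5 passed in 16 of 29 settings, Slpi in 11, Zfp608 in 13 and Trim55 in 12 of 25, while Ccl1 and Csf1 passed in 28 of 29. Of 100 drawn splits of mutant and WT arrays within each time, 5 gave as many genes, the real split included, with up to 309 in another split, so chance is not excluded for the count of 164. With the labelled sex in the model Trim12a, Dapl1, Adh1, Lgals3, Gata3 and Nfil3 stayed past the threshold, and Gzma (4.15), Efna5 (4.18), Ccl1 (3.84), Csf1 (3.58) and Slpi (3.68) did not.

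The set of 1070 genes called in 4-week Y136F cells was weighed against technical and sampling explanations; with an estimated correlation the proliferation list kept its call (adjusted p = 0.005), and the memory and effector (0.053) and Th2 lists (0.12) did not. Sex of the mice as the whole cause is argued against by the female Y136F mice of both times: genes called without 1 of the 4-week Y136F arrays (703, 669 and 598) differed in that array from the 1-week Y136F arrays by medians of 1.05, 1.19 and 1.35 (lower quartiles 0.37, 0.57 and 0.83) in the direction of the difference from WT, whose median sizes were 1.3, 1.41 and 1.51, while the same medians between 1-week Y136F arrays were -0.11 to 0.14. A lower share of T cells with all other cells raised alike is argued against by the B cell list. Its median was -0.25 (quartiles -0.45 and 0.41), beside 0.83 for the plasma cell list. A rise of single other cell types, plasma cells among them, is not covered by this. A difference in the percent of spots well above background is argued against by the 996 genes that stayed called with that percent in the model. For mast cells or basophils as the source of Cpa3, Hdc and Hrh4 (3.23 to 3.98), limma called 0 of 10 other marker genes higher (median -0.1, upper quartile 0.78). As a set these argue against a source that raised all markers alike. The list pools both cell types, and the 2 markers with an unadjusted p under 0.05, Cma1 (0.89) and Mcpt4 (0.99), were higher. A source in either cell type alone, or in a small share of them, thus stays open. Plasma cells in the sort stay open too, since 0 immunoglobulin constant region genes carried a name to test. The CD44low CD4+ gate would be expected to remove plasma cells. Activated or dividing CD4+ T cells in the sorted gate, as the genotype may produce over time, are a candidate explanation that the data leave open, as is a sex difference that arises only by 4 weeks, since no 4-week WT mouse was labelled female.

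Trim12a was near the level of other groups in 15 arrays (2.64 to 3.78) and at -2.88, -3.03 and -3.93 in the 4-week Y136F arrays. A fault of 1 slide or spot is argued against by the 3 slides that hold these arrays, with 0 outlier spots at the probe. A wide stretch of another strain's chromosome around the gene stays open: 1 of the 50 nearest measured genes was called, 2% against 4.05% of other named genes (one-sided Fisher's exact p = 0.87, upper 95% limit of the odds ratio 2.84), and that gene, Trim12c, lay at -2.35 to -1.95 in these 3 arrays and at -1.64 to -0.44 in the 15 others. Trim12a lies on chromosome 7 like Lat, with 250 measured genes between them. A narrow allele difference under the probe, carried by these 3 mice and not by the 1-week Y136F mice, may also explain the loss, as its second probe fell by 1.42 only; no biological explanation was tested.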

How the results depend on the processing

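The kept outlier spots, the brightness term and the 2 sets of left-out arrays were chosen after the results were seen. No named gene reversed in the settings run for single genes, which leave out the one with female mice only. For LAT KO against WT at 1 week (6 genes), 0 passed with only its groups in the model, 146 with array weights, 10 with the brightness term and 10 without both LAT KO arrays whose sex-linked genes contradict their label. It was 4 to 9 without single arrays. At 4 weeks (31) it was 47 with slide as a random block (correlation 0.1), 7 with no trend, 4017 with weights and 17 without those 2 arrays, and 5 to 38 without single arrays. Y136F against WT at 1 week (5) gave 3 with quantile normalization, 2 with the series matrix, 13 and 9 with slide random and fixed, 406 with weights, 11 with the replicate block, 0 with female mice only, 3 with outlier spots kept and 21 without the 2 arrays (2 to 4 without single arrays). At 4 weeks (1070) it was 85 with sex in the model, 4901 with weights and 562 to 1206 without single arrays. LAT KO against Y136F at 1 week (0) gave 1 with normexp, 2 with quantile, 1 with only its groups, 144 with weights, 1 with the replicate block and 1 with the brightness term (0 to 0 without single arrays). At 4 weeks (1063) it was 681 with slide fixed, 167 with sex, 2334 with weights and 441 to 862 without single arrays. The LAT KO change over time (0) gave 5 with weights, 2 without the 2 arrays and 0 to 1 without single arrays. That of Y136F (164) gave 50 with sex, 484 with only its groups, 99 with no trend, 1303 with weights, 572 without the 2 arrays and 61 to 161. WT over time (0) gave 3 with only its groups, 2003 with weights, 4 without the LAT KO array of most outlier spots, 167 without the 2 arrays and 0 to 0. The r of the 2 mutant effects at 4 weeks reversed from 0.55 to -0.07 with sex; this term used the labelled sex, rests on the 1-week WT and LAT KO groups, and 2 LAT KO arrays contradict it. The replicate block gave 5, 28, 1068, 976, 0, 162 and 0 genes in the other comparisons, in the order above. No comparison had all pairing correlations above 0.1, but with 3 arrays per group this cannot exclude pairing. At 4 weeks replicate 1 of WT, LAT KO and Y136F shared slide 4, and replicate 3 shared slide 3. List tests past the threshold went from 110 to 16 with an estimated correlation. Array weights ranged from 0.27 to 3.51. The causes of these shifts were not tested. Dim spots limit depth in WT replicate 1 of 1 week most (84.2% well above background).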

Other observations

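The tests on the 2 LAT KO arrays and on brightness were chosen after the results were seen; the splits of the arrays were chosen before.

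Sex-linked genes contradicted the label of 2 LAT KO arrays. The array labelled LAT KO 1 week replicate 1, female, had Xist at -9.3 and Y-linked Ddx3y at -0.23, and the array labelled LAT KO 4 weeks replicate 2, male, had Xist at 0.21 and Ddx3y at -8.92; other female labels lay at -0.19 to 0.74 for Xist and -9.03 to -8.27 for Ddx3y. A mixture of male and female RNA is argued against by Xist at -9.3 in the former, below the other male labels (-7.99 to -3.74), and by Ddx3y within the female range in the latter. An exchange of the 2 arrays between the time points and a wrong sex entry cannot be told apart: 1 of the 2 arrays correlated better with both LAT KO arrays of the opposite time, and 0 of the 2 with both of its own time. An exchange would match both sex labels. Slide 1 would then hold only 1-week arrays and slide 3 only 4-week arrays. Slides 2 and 4 held both times, so the layout does not decide. Signals of the 1-week array correlated at 0.9827 and 0.9807 with the LAT KO arrays of the opposite time, and at 0.9755 and 0.955 with its own. For the 4-week array it was 0.9913 and 0.9684, and 0.9801 and 0.9777. Mean correlations of deviations from gene means were -0.12 with the opposite and -0.34 with the own time for the 1-week array. For the 4-week array they were 0.13 and -0.4. The 1-week array was nevertheless about as close to 1 array of its own time (-0.03) as to 1 of the opposite time (-0.05). If the arrays were exchanged, the LAT KO comparisons of each time would hold 1 mouse of the other, and the 1-week count without both arrays was 10, the 4-week count 17.

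In 2 other arrays labelled male, WT 1 week replicate 3 and LAT KO 1 week replicate 3, both on slide 1, Xist was well above background at -3.98 and -3.74. The male labels of 4 weeks, but for LAT KO replicate 2, lay at -7.99 to -7.03, not well above background. The other arrays of slide 1, Y136F 1 week replicate 1 and LAT KO 4 weeks replicate 2, had high Xist (0.32 and 0.21). Ddx3y was at 0.04 and -0.41 in these 2 arrays, as in other male labels. A small share of female RNA, or of signal from another array, stays open for them and was not tested.

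For LAT KO against WT at 1 week, 4 of the 10 splits of the 6 arrays gave at least the 6 genes of the real split, and the highest other gave 4747. That split set the arrays of slides 3, 4 and 5 against those of slides 1 and 2. It also set arrays with fewer spots well above background (84.2%, 91.4% and 89.3%) against those with more (95.6%, 96.5% and 97.9%). This points to a structure of the samples. The 75th percentile of the signal did not separate them (1444.7, 1524.6 and 1326.2 against 1250.1, 1648.1 and 1410). With slide as a fixed term 4 genes passed in the real comparison, as a random block 6, and with the percent of spots well above background as a term 10. The other comparisons of 3 against 3 arrays have too few splits for a share under 0.05: LAT KO against WT at 4 weeks gave 31 (highest other 0), Y136F against WT 5 and 1070 (0 and 0), LAT KO against Y136F 0 at 1 week (7) and 1063 at 4 weeks (0), and WT over time 0 (0). As many genes as the real split came from 1 split in each of these but LAT KO against Y136F at 1 week and WT over time, where it was 10 of 10. For the LAT KO change over time 100 of 100 drawn splits gave at least the 0 genes found, with up to 3133.

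The percent of spots well above background went with the main axis of variation. It comes from the same scans and is not the signal level of an array. WT replicate 3 of 4 weeks had the lowest 75th percentile (1123.7) with 94.5% of spots well above background. The first principal component held 49.5% of the variance and the second 15.9%, and the first correlated with the percent of spots well above background over the 18 arrays (r = 0.85, permutation p = 1e-05, the smallest 100000 permutations can give; rho = 0.78, p = 2e-04). Without the 2 arrays farthest from the median r was 0.76.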
